A study of Brassica napus with 6 samples.

How the data were processed

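Small RNA was sequenced from young pistils and siliques of rapeseed (Brassica napus) in a line with long siliques (LS) and a line with short siliques (SS), 2 libraries per line, and the degradome in 1 library per line. Per the labels, both lines were backcross progeny of one cross, tissue was taken from 0 to 7 days after pollination from about 12 plants per stage, and tissue came from a pair of replicated experiments. Small RNAs of 18 to 30 nt were taken from 10 µg of total RNA for each small RNA library, and each degradome library started from about 200 µg, per the labels' protocols.

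The authors deposited, for each numbered pair of an LS and an SS library, a table of known miRNAs and a table of predicted miRNAs, named novel_mir with a running number. Per the file headers, each table holds the read count of each miRNA and the total of the library, and the deposited counts are whole numbers that were not normalized. The deposited RPM values were the count divided by the library total and multiplied by 1000000, with 0.01 written where the count was 0. Per the file headers, the log2 fold change in the authors' tables is SS over LS, and the p-value beside it compares 1 library with 1 library. The test behind that p-value, the aligner, the miRNA database and the genome build are not given in the sources used here, nor is the kind of read that the library total counts. The deposited degradome tables list, for each miRNA and mRNA pair, a position in the mRNA, an alignment score, a category from 0 to 4 and a p-value, with the paired sequences but without read numbers at the site. The names of the known miRNAs carry species prefixes (ath, bra, bna and others), and near-identical members of a family can share reads in a way the files do not resolve.

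All else was computed from the deposited counts. Of 69 known miRNAs in 39 families, none had the same counts as another in all 4 libraries, so no features were merged. The main test was edgeR 4.0.16 (quasi-likelihood, TMM factors, two-sided) in R 4.3.3 on miRNAs with 10 or more counts in at least 2 libraries, which left 52 miRNAs and, after summing members, 32 families. The threshold was a Benjamini-Hochberg adjusted p of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. The 8 lists of families, the tests, the rule for named miRNAs and most alternatives were fixed before the data were examined. Named miRNAs were up to 24 past the test by smallest p, the most abundant member of each listed family with enough counts, and the 5 most abundant miRNAs. Named families were up to 12 past the test, and miR398, miR166, miR171 and miR167 were chosen after their values were seen. Named predicted miRNAs were the 3 with the highest summed count in each pair. For the degradome, the rule took the target with the smallest p per family and library (ties by the lower score), and a selection of these is printed. Its other part, the 5 entries with the most reads at the site, was not applied, since the tables used here give no such reads. Lists were tested with camera (limma 3.58.1, preset correlation of 0.01, then an estimated one) and with fry.

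The alternatives were RLE factors, the authors' library totals, no factor, no filter, 50 counts in 2 libraries, DESeq2 1.42.0 with a local dispersion fit, limma-voom, the replicate number as a block, and each library left out in turn. With 1 library left in a line, that library was assumed to vary like those of the other line. The libraries of a line were compared with a chi-square test of their counts given the library totals. The LS libraries differed by no more than counting noise and were counted as 1 sample, so LS levels are the mean of both with a 95% Poisson interval of the summed counts, and SS levels are mean ± SD with n = 2. Intervals and the floor of 3 counts over both libraries of a line used for a count of 0 cover counting error only. The main test kept the LS libraries as separate samples, and its p-values and standard errors are printed unless another fit is named. Fits with the LS libraries summed into 1 sample were chosen after the data were seen.

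The predicted miRNAs carry no sequence or position in the count tables, so the planned test across pairs was not made, and a test by shared running number was added after the data were seen. In the degradome tables, sequences are printed 5′ to 3′ as DNA letters. The LS table stops inside its last entry while its targets run in ascending order, so the libraries were also compared up to the last target of the LS table. None of the 471 target identifiers matched the gene table used here, so targets carry identifiers without gene names or coordinates.

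The test was checked on simulated counts with the means and library sizes of the 52 tested miRNAs, with 12 of them changed in each of 50 rounds. The 5 most abundant miRNAs were never among those changed, and as many changes went up as down. The rates below therefore do not cover an error of the scaling between the lines. At a dispersion of 1e-04, 86.2% of 2-fold, 63.7% of 1.5-fold and 51.3% of 1.25-fold changes were called, and 0.945% of unchanged miRNAs. For the real libraries edgeR gave 9.77e-05, the lower end of the range it searches. That value is a limit of the estimate and not a measured spread. At a dispersion of 0.02 the test called 56.5% of 2-fold changes and 0.418% of unchanged miRNAs. Summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.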

Results

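The data covered 4 small RNA libraries, 2 from the long-silique line (LS) and 2 from the short-silique line (SS), and 2 degradome libraries, 1 per line. The silique is the seed pod of rapeseed, and a degradome library holds the 5′ ends of cut mRNAs, which mark sites where a miRNA directs cleavage. The authors' library totals were 6409382 and 6739286 reads in the LS libraries and 6046506 and 6403019 in the SS libraries. Known miRNAs took 4.82% of the total in each LS library (Wilson 95% intervals 4.81% to 4.84% and 4.80% to 4.84%), 6.51% in SS library 1 (6.49% to 6.53%) and 6.50% in SS library 2 (6.48% to 6.52%). In every library the same 4 miRNAs, smo-miR156c, ath-miR167a-5p, ath-miR166a-3p and bra-miR158-5p, held between 80.7% and 81.5% of the known miRNA reads. The counts of known miRNAs in the LS libraries differed by less than the sampling noise (chi-square 0.98 per degree of freedom, p = 0.531 from 10000 draws of the exact binomial distribution), and these libraries were counted as 1 sample. Those of the SS libraries differed by slightly more (1.42 per degree of freedom, p = 0.0104 from draws of the exact binomial distribution), but the counts of predicted miRNAs in the SS libraries did not (0.881, p = 0.974 from such exact draws). The p-values below measure only the spread between these libraries, which may be technical, although the labels speak of replicated experiments. Unless another fit is named, p-values and standard errors for SS against LS come from fits that kept the LS libraries as separate samples. They do not follow the count of LS as 1 sample and may be too small.

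The first comparison asked which known miRNAs differ in abundance between young siliques of the lines. Most tested members of the miR156 and miR157 families, which act on SPL transcription factors in the change from juvenile to adult growth, were higher in SS. ath-miR157a-5p stood at 1149 ± 26.2 RPM in SS (SD, n = 2) and at 435 RPM in LS (counting interval 424 to 447), 2.64-fold higher. ath-miR408-5p, from a family that acts on copper proteins, stood at 477 ± 9.53 RPM in SS against 178 RPM in LS (170 to 185), and ath-miR164a, which acts on NAC genes of organ boundaries, at 1011 ± 5.61 RPM against 459 RPM (448 to 471). In the other direction, ath-miR159a, which acts on GAMYB-like genes, stood at 46.2 ± 4.72 RPM in SS against 131 RPM in LS (124 to 137), 2.83-fold lower. ath-miR160a-5p, which acts on auxin response factors, stood at 2.26 ± 0.773 RPM against 12.7 RPM (10.8 to 14.8).

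**Figure D1:**
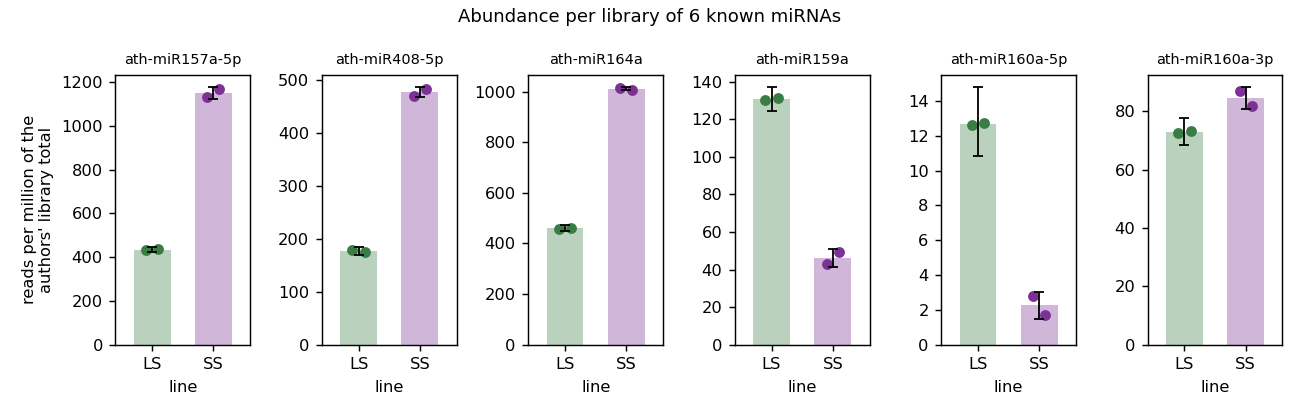
RPM by the authors' library total (y axis, from 0) in LS and SS for 6 known miRNAs, with points for libraries, bars for means, and error bars for the counting interval in LS and the SD in SS. ath-miR157a-5p, ath-miR408-5p and ath-miR164a lie higher in both SS libraries, and ath-miR159a and ath-miR160a-5p lower, while ath-miR160a-3p is at 73.1 RPM in LS and 84.5 ± 3.76 RPM in SS.

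By edgeR's quasi-likelihood test with TMM scaling, 27 of the 52 tested miRNAs passed the adjusted threshold, 18 higher and 9 lower in SS. With the LS libraries counted as 1 sample, 23 of these passed, 16 higher and 7 lower, and the calls of ath-miR164c-5p, ath-miR171a-3p, ptc-miR167f-5p and bra-miR2111b-3p ended. With the authors' library totals, 36 passed, of which 33 were higher and 3 lower, and the median log2 fold change of the tested miRNAs was 0.41 with this scaling and 0.12 with TMM. DESeq2 called 17 of the 27, 10 higher and 7 lower, without those 4, ahy-miR156c, ath-miR167a-5p, bna-miR167d, bna-miR2111c, bra-miR9553-5p and gma-miR172h-5p. Changes below are relative to the TMM scale unless another is named. The direction and the call of 13 miRNAs held in every setting that tested them. Of these, 10 were higher in SS (ath-miR156a-5p, ath-miR157a-5p, ath-miR164a, ath-miR390a-5p, ath-miR391-5p, ath-miR408-5p, bra-miR5654a, ghr-miR827a, ptc-miR156k and smo-miR156c) and 3 lower (ath-miR159a, ath-miR160a-5p and bol-miR398a-5p).

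The list of phase and flower identity families (miR156, miR157 and miR172) had 6 of 9 members higher and none lower, and 6 when adjusted over the list alone. ptc-miR156k had a log2 fold change of 1.80 ± 0.20 (SE, edgeR adjusted p = 7.38e-14), ath-miR157a-5p 1.10 ± 0.04 (4.71e-52), and smo-miR156c, the most abundant miRNA in SS, 0.35 ± 0.01 (7.93e-82). ath-miR172a, from a family that acts on AP2-like genes, did not pass at -0.03 ± 0.04 (edgeR adjusted p = 0.631), and it was higher with the authors' library totals at 0.27. ath-miR172c was at -0.01 without a call. gma-miR172h-5p, with 3 and 6 counts in LS and 17 and 10 in SS, rose by 1.34 (edgeR adjusted p = 0.0238). Its name denotes the 5′ arm, the strand opposite to the usual guide of miR172. Its call ended with RLE factors, with DESeq2 and with the replicate number as a block. By camera the list did not pass (adjusted p = 0.19, and adjusted p = 0.69 with an estimated correlation).

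The auxin list (miR160, miR167, miR390 and miR393) had 4 of 8 members higher and 1 lower, with 5 past when adjusted over the list alone. ath-miR390a-5p, which starts the tasiRNAs against auxin response factors, rose by 0.33 ± 0.04 (SE, edgeR adjusted p = 5.89e-15), and ath-miR167a-5p rose by 0.15 ± 0.01 (5.57e-44). The calls of ath-miR167a-5p and ptc-miR167f-5p (0.11 ± 0.04) ended with RLE factors and with no factor, where the latter was at -0.023. ath-miR160a-5p fell by 2.78 ± 0.27 (7.1e-17), whereas the opposite arm ath-miR160a-3p was at -0.09 ± 0.05 (edgeR adjusted p = 0.258), and at 0.21 and past the test with the authors' library totals. The list's median was 0.11, its mean -0.27, and camera gave it a direction upwards (adjusted p = 0.972, and adjusted p = 0.975 with an estimated correlation).

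The list of organ growth and boundary families had 2 of 4 members higher and 2 lower, and 4 when adjusted over the list alone. ath-miR164a rose by 0.84 ± 0.04 (SE, edgeR adjusted p = 4.41e-42) and ath-miR164c-5p by 0.27 ± 0.08 (0.00671). The call of ath-miR164c-5p ended with the LS libraries as 1 sample (edgeR adjusted p = 0.0615), which left 1 of 4 members higher, and also with RLE factors, with no factor and with DESeq2. ath-miR166a-3p and ath-miR165a-3p, which act on HD-ZIP genes of leaf and organ polarity, fell by 0.03 and 0.11 on the log2 scale, but with the authors' library totals they were higher by 0.26 and 0.18, and ath-miR166a-3p was also above 0 without the filter at 0.014. Camera gave this list an adjusted p = 0.972, and adjusted p = 0.975 with an estimated correlation.

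Among the list of gibberellin-linked and other transcription factor families, none of 7 members was higher and 2 were lower, and 2 when adjusted over the list alone, against 1 higher (ath-miR169b-5p at 0.75) and 1 lower with the authors' library totals. ath-miR159a fell by 1.79 ± 0.05 (SE, edgeR adjusted p = 5.39e-56) and ath-miR171a-3p, which acts on GRAS genes, by 0.31 ± 0.10 (0.00917). The call of ath-miR171a-3p was lost with the authors' library totals, where it was at -0.02. Camera gave the list an adjusted p = 0.19 (0.69 as adjusted p with an estimated correlation), and with the authors' library totals an adjusted p = 0.0438 for a lower position than the other miRNAs (0.543 as adjusted p with an estimated correlation), while the list's median log2 fold change with these totals was 0.08.

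The copper and redox list had 1 of 3 members higher, 1 lower, and 2 past when adjusted over the list alone. ath-miR408-5p rose by 1.13 ± 0.04 (SE, edgeR adjusted p = 3.25e-52). bol-miR398a-5p, from a family that acts on copper superoxide dismutases, had 24 counts in LS and 3 in SS, a ratio of 7.57 (exact counting interval 2.30 to 39.3). Both names denote the 5′ arm, which is the strand opposite to the usual guide of these families. The phosphate and sulfate list had 2 of 6 members higher, 1 lower, and 4 past when adjusted over the list alone. In it ghr-miR827a rose by 0.89 ± 0.13. bna-miR2111c, with 7 and 2 counts in LS and 12 and 16 in SS, rose by 1.40 ± 0.53 (2.56 without LS library 1 and 0.74 without LS library 2). The call of bna-miR2111c ended with DESeq2 and with the replicate number as a block. bra-miR2111b-3p fell by 0.94 ± 0.35, a call that ended with the authors' library totals. nta-miR168a, which acts on ARGONAUTE mRNA, fell by 0.25 ± 0.02 as the 1 of 3 small RNA pathway members past the test, 1 also when adjusted over the list alone, and was higher with the authors' library totals at 0.049. ath-miR162a-3p and ath-miR403-3p of that list were at 0.11 and 0.03 without a call, and with the authors' library totals 2 of the 3 members were higher (ath-miR162a-3p at 0.41 beside nta-miR168a) and none lower. None of the 5 members of the Brassicaceae list passed, nor did any when adjusted over the list alone, with log2 fold changes of 0.57 for bna-miR6033, 0.08 for bna-miR6030, 0.02 for bna-miR6029, -0.05 for bna-miR161 and -0.08 for bna-miR6028. With the authors' library totals, 3 of these 5 were higher, 3 also when adjusted over the list alone (bna-miR6033 at 0.86, bna-miR6030 at 0.37 and bna-miR6029 at 0.32), and bna-miR161 and bna-miR6028 were above 0 without a call at 0.24 and 0.22. Camera adjusted p was 0.972 for the copper, phosphate and Brassicaceae lists and 0.589 for the small RNA pathway list (0.975 and 0.9 as adjusted p with an estimated correlation).

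**Figure D2:**
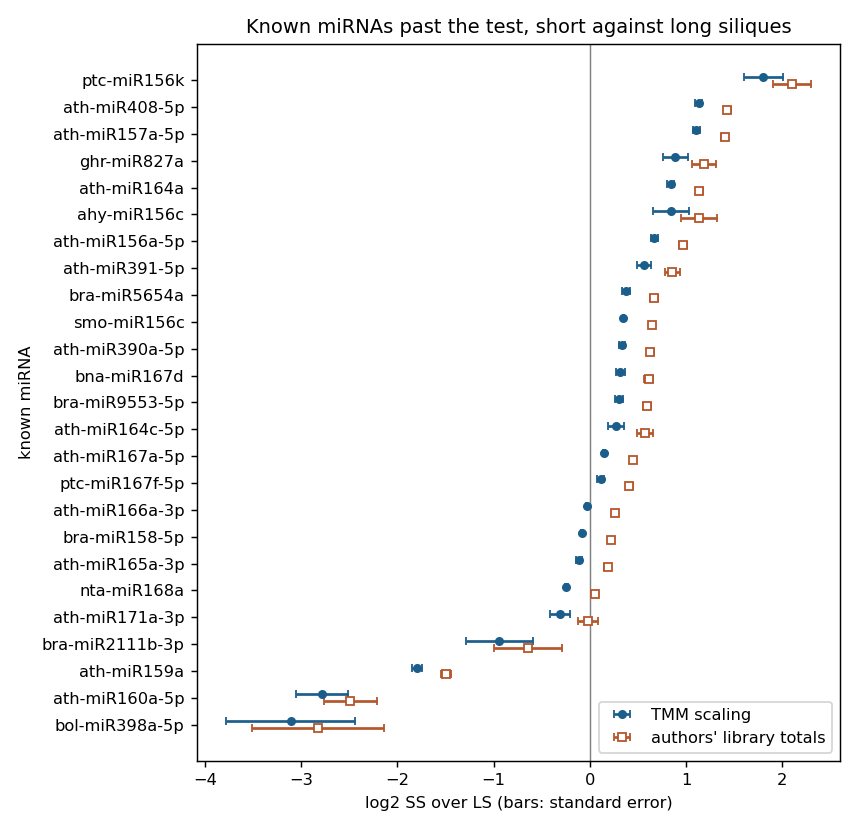
log2 fold change of SS over LS (x axis) with standard errors for the named known miRNAs past the test (y axis), with TMM scaling (filled circles) and with the authors' library totals (open squares). All points shift to the right with the totals, and nta-miR168a, ath-miR165a-3p, bra-miR158-5p and ath-miR166a-3p cross 0, while ath-miR159a, ath-miR160a-5p and bol-miR398a-5p stay below -1.

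Camera with the preset correlation passed 0 of the 8 lists, as with an estimated one, and 2 lists had an unadjusted p under 0.05 (0.0296 for phase and flower identity, 0.0475 for the gibberellin-linked list). By fry, which tests a list's own members for a joint shift, 6 of the 8 lists passed. With the authors' library totals 8 passed, and the small RNA pathway list turned from lower to higher. With the LS libraries as 1 sample the auxin list no longer passed. A pass did not mean that all members moved one way. The organ growth list had 2 members higher and 2 lower with a fry direction upwards. The auxin and copper lists had means of -0.27 and -0.63, also with a fry direction upwards. Calls of ath-miR166a-3p, ath-miR171a-3p, ath-miR165a-3p, ath-miR164c-5p, ahy-miR156c, ptc-miR167f-5p, bna-miR2111c, bra-miR2111b-3p and gma-miR172h-5p each ended in 1 or more of the fits that left out a library.

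Summed by family, miR157, miR408, miR827 and miR164 rose in SS and miR159 and miR398 fell. The log2 fold change was 1.03 ± 0.03 for miR157 (SE, edgeR adjusted p = 1.17e-38), 1.05 ± 0.04 for miR408, 0.81 ± 0.13 for miR827 and 0.73 ± 0.03 for miR164. It was 0.28 ± 0.03 for miR156 and 0.26 ± 0.03 for miR390. miR159 fell by 1.87 ± 0.07 (1.58e-33). miR398 fell by 2.36 ± 0.25 (5.37e-05), a call that ended with DESeq2 (DESeq2 adjusted p = 0.116), and it was too low to be tested at 50 counts in 2 libraries. miR168, miR165, miR158 and miR166 fell by 0.32, 0.19, 0.15 and 0.11, and were higher with the authors' library totals at 0.049, 0.18, 0.22 and 0.26. miR160 fell by 0.36 ± 0.07 and miR171 by 0.30 ± 0.08, but with those totals they did not pass, at 0.014 and 0.074. The family sums take every arm that was counted. For miR408 and miR398 all counted names denote the 5′ arm, opposite to the usual guide, so these sums do not measure the guide strand. For miR160, ath-miR160a-3p held 466 of 609 reads in LS library 1 and 527 of 606 in SS library 1, so the sum mostly follows that arm. With the arms kept apart, 22 of 43 sums passed edgeR's test, 15 higher and 7 lower. The call of miR167 (0.07 ± 0.03) ended with no factor. In all, 18 of 32 families passed edgeR's test, 10 higher and 8 lower, against 22 higher and 2 lower with the authors' library totals and 11 higher and 8 lower with the LS libraries as 1 sample.

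ath-miR157a-5p, ath-miR164a and ath-miR408-5p were higher in SS, and ath-miR159a and ath-miR160a-5p lower, in both numbered pairs of libraries. Across 52 miRNAs, the log2 ratio of SS to LS by the authors' library totals had a Pearson correlation of 0.78 between the pair numbered 1 and that numbered 2, and 46 miRNAs had the same sign in both, 42 higher and 4 lower in SS. With these totals the median log2 fold change was 0.41, so a shared sign can come from this common shift. With the pairs crossed the correlation was 0.86 and 47 miRNAs had the same sign, so the agreement was not tied to the numbering. miRNAs are not independent replicates, so these correlations describe these libraries.

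In the authors' deposited tables of known miRNAs, 14 miRNAs were marked as changed in each pair and 10 in both. The 10 were ath-miR157a-5p, ath-miR164a, ath-miR408-5p, ghr-miR827a and ptc-miR156k, higher in SS, and ath-miR159a, ath-miR160a-5p, ath-miR319a, ath-miR394a and bol-miR398a-5p, lower in SS. ath-miR319a, which acts on TCP genes of organ growth, had 6 counts in each LS library and 0 in both SS libraries, at least 1.96-fold lower from the lower limit of the LS counting interval (0.472 RPM) to a floor of 3 counts over both SS libraries (0.241 RPM). ath-miR394a, which acts on an F-box gene, had 8 and 10 counts in LS and 1 in each SS library. Both lay under the count filter of the test above.

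The predicted miRNAs were not tested across pairs as planned. novel_mir_1 was the most abundant in both pairs, at 92.5 RPM in LS and 94.9 RPM in SS in pair 1, and at 87.8 and 91.7 RPM in pair 2. novel_mir_2 stood at 52.6 and 59.9 RPM in pair 1 and at 50.3 and 63.4 RPM in pair 2, and novel_mir_3 at 42.0 and 65.0 RPM and at 47.9 and 68.9 RPM. Chosen after its values were seen, novel_mir_11 had 45 and 28 counts in the LS libraries and 0 in both SS libraries, at least 18.1-fold lower by the same limit and floor. novel_mir_22, chosen likewise, had 29 and 34 counts in LS and 6 and 10 in SS, 3.75-fold lower in RPM. No predicted miRNA listed in both pairs had a count of 0 in LS library 1, so none could stand as found in SS alone. In the authors' deposited tables, pair 1 had 12 marked predicted miRNAs and pair 2 had 20, with 3 in both (novel_mir_11, novel_mir_22 and novel_mir_212). Some marks in pair 1 disagree with the fold change and p-value beside them. By those values the counts were 13 and 20, with 4 in both, novel_mir_87 being the addition. Matched by running number, 8 of 67 passed edgeR's test, but 0 with the LS libraries as 1 sample and 0 without LS library 2, where 10 and 9 had an unadjusted p under 0.05. DESeq2 called 7. By this match novel_mir_1 was lower in SS on the TMM scale at -0.26 ± 0.07 (edgeR adjusted p = 0.00449), but at 0.049 and not past the test with the authors' library totals (edgeR adjusted p = 0.654).

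Degradome targets were compared to see which mRNAs were cut in each line. Targets of miR156, miR159, miR160, miR164, miR171, miR172 and miR319 were found in both libraries, though for some of these families not all targets were shared. Each line had 1 library and no replicate check. The LS table held 95 entries of known and 67 of predicted miRNAs, and the SS table held 382 and 195. The LS table stops inside an entry, however, and up to its last target the SS table held 128 and 65. Over this range 15 families had entries in LS and 17 in SS, and 53 of the 57 pairs of a known family and a target in LS were also in SS. Category 0, the strongest class of site, held 105 of the LS entries (64.8%, exact 95% interval 56.9% to 72.1%) and 106 of the SS entries (54.9%, 47.6% to 62.1%). Several miRNAs can share a site, and these entries lay at 68 sites in LS and 65 in SS. Intervals over entries take them as independent and are therefore too narrow. Category 1 held 11 and 24, category 2 held 10 and 41, category 3 held 11 and 18, and category 4 held 25 and 4. Without ahy-miR156c, which gave 20 of the SS entries of category 2, this category held 10 and 21, and the shares of category 0 were 63.9% (exact 95% interval 55.9% to 71.4%) and 61.3% (53.6% to 68.6%).

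**Figure D3:**
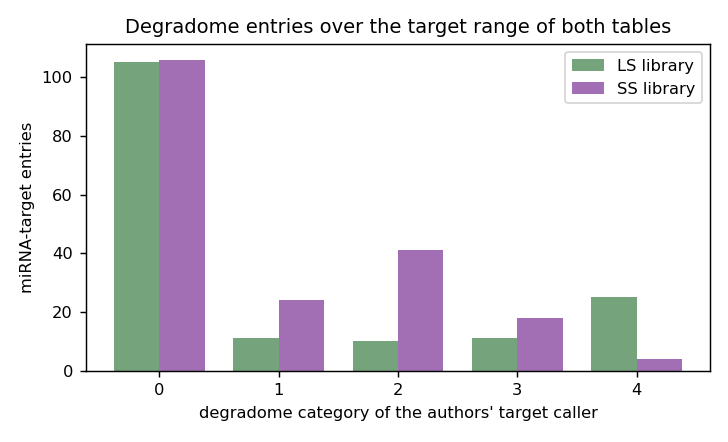
Number of miRNA-target entries (y axis, from 0) by degradome category (x axis) in the LS and SS libraries, up to the last target of the LS table. Category 0 holds 105 and 106 entries, category 1 holds 11 and 24, category 2 holds 10 and 41 (10 and 21 without ahy-miR156c), category 3 holds 11 and 18, and category 4 holds 25 and 4.

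Among families past the test of abundance, miR156, miR159, miR160, miR164, miR166, miR168 and miR171 had targets in both libraries over this range, miR390 had 0 in LS and 1 in SS, and miR5654 had 0 in each. The other 9 had no entry under their own names in either table. Among them were miR157 and miR165, which act on the same kinds of genes as miR156 and miR166. The lack of an entry therefore does not show that their targets were uncut. miR159, lower in SS by 1.87, had 5 targets in LS and 4 in SS, 4 of them shared. miR160 had 3 in each library and miR164, higher in SS by 0.73, had 6 in each, all shared. miR319, with no read in the SS small RNA libraries, had 5 targets in LS and 6 in SS, 5 of them shared. The miR159 site with the smallest p lay at position 549 of BnaA03g15690D in both libraries, category 0, where bra-miR159a (TTTGGATTGAAGGGAGCTCTA) faces TAGAGCCCCCTTCAAACCAAA. That of miR160 lay at position 1297 of BnaA07g20790D, category 0 in both, where bna-miR160d (TGCCTGGCTCCCTGTATGCCA) faces TGGCATGCAGGGAGCCAGGCA. That of miR164 lay at position 816 of BnaA02g09970D and that of miR156 at position 737 of BnaA02g14580D, again category 0 in both. miR156 had 10 targets in LS and 28 in SS over the shared range, but 9 and 11 without ahy-miR156c, whose 73 entries in the whole SS table were all of category 2 with a p of 0.002. The miRNA names of the degradome tables are partly others than those of the count tables, so levels were set beside targets by family only, with all counted arms summed. Numbers of targets do not measure how much of an mRNA was cut, since no reads at the site are given.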

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

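The fits with the LS libraries as 1 sample, the crossed pairing, the matching of predicted miRNAs by running number and the degradome comparison up to the last LS target were chosen after seeing the data. So was the fit with the arms of a family kept apart. Of 27 known miRNAs called, 13 kept direction and call in each of the settings that tested them, and 10 of 18 families did. DESeq2 called 17 known miRNAs, 10 higher and 7 lower, all among the 27, and the cause was not tested. The other known miRNA and family counts stayed within 1.5 times the main count.

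The authors' library totals, by raising every log2 fold change, turned the sign of the following values. Past the test with both scalings were nta-miR168a 0.049, bra-miR158-5p 0.22, ath-miR166a-3p 0.26, ath-miR165a-3p 0.18, miR168 0.049, miR165 0.18, miR158 0.22 and miR166 0.26. Past it with TMM only were miR160 0.014, miR171 0.074 and novel_mir_1 0.049. Past it with the totals only were ath-miR172a 0.27, ath-miR160a-3p 0.21 and novel_mir_2 0.26. With the LS libraries also as 1 sample the known miRNAs and families gave these values again to 2 decimals. ath-miR166a-3p was at 0.014 with no filter on low counts, and ptc-miR167f-5p at -0.023 with no factor. The same totals gave 1 list past camera's threshold, the gibberellin-linked one (adjusted p = 0.0438, and adjusted p = 0.543 with an estimated correlation).

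The labels do not say that a replicate number ties an LS to an SS library. With the replicate block edgeR called 23 known miRNAs (14 higher, 9 lower), 18 families (9 higher, 9 lower, without miR167), 0 lists by camera and 3 by fry against 6, with the auxin, copper and small RNA pathway lists no longer past (fry adjusted p = 0.0506, 0.0565 and 0.0791). Deviations of same-numbered libraries had a correlation of -0.26 across miRNAs, and with the pairing crossed 25 known miRNAs and 18 families were called.

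Leaving out 1 library gave 20 to 24 known miRNAs and 18 to 20 families. For predicted miRNAs matched by running number it gave 0 to 5 against 8, with 0 for the LS libraries as 1 sample and 3 with no filter. Between pairs the correlation was 0.96 with 50 counts in 2 libraries. Of the marks on predicted miRNAs, 1 was in both pairs after Benjamini-Hochberg adjustment. For these the cause was not tested. The fit of known with predicted miRNAs together was not run, since the tables do not pair the latter by sequence.

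Entries in SS per entry in LS came to 3.56, and to 2.90 for category 0. Up to the last LS target the ratio was 1.19, with 1.01 for category 0, 1.35 for known miRNAs and 1.09 without ahy-miR156c, so most of the excess lies past the end of the LS table. Of the LS combinations of family and target, 61.3% were in SS, 75.0% for category 0 and 93.0% for known miRNAs, and the cause was not tested. Counting noise limits miRNAs of few reads, since the floor of 3 counts over both SS libraries equals 0.241 RPM.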

Other observations

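The tests of the technical explanations were chosen after the results were seen, while the edgeR fold changes come from the planned test. Some miRNAs without a place in the fixed lists also differed. ath-miR391-5p stood at 58.7 ± 0.917 RPM in SS (SD, n = 2) against 32.4 RPM in LS, and bra-miR9553-5p at 181 ± 2.34 against 120 RPM. The edgeR log2 fold changes were 0.56 ± 0.08 (SE) and 0.30 ± 0.04, and that of bra-miR5654a was 0.37 ± 0.04. The arms of ath-miR160a moved apart: reads of the 5′ arm were 17.4% of those of the 3′ arm in each LS library, and 3.23% and 2.10% in the SS libraries. The degradome entries of miR160 numbered 3 in each library up to the last LS target. Without read numbers at the site, this number does not measure the amount of cleavage. novel_mir_11, without a read in the SS count tables, is a name that also occurs in the degradome tables, with 4 entries in LS and 5 in SS over that range, and whether the name marks the same RNA in both kinds of table is not given in the sources used here. In the authors' deposited table of predicted miRNAs for pair 1, 9 marks disagreed with the table's own fold change and p-value, and none did in the other tables.

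The libraries of a line were closely alike. For LS the chi-square per degree of freedom over known miRNAs was 0.98, which a single library read again or one RNA pool may give. For SS a single library read again stays open: over known miRNAs the value was 1.42, above the upper limit of 1.36, and 1.61 over those with at least 10 summed counts (p = 0.0035 from draws of the exact binomial distribution, and p = 0.0234 from such exact draws with at least 50), which goes against it, but over predicted miRNAs it was 0.881, and 0.837 and 0.630 with these minimums. Closely alike tissue samples from replicated experiments stay open as well and were not tested.

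Predicted miRNAs had a median log2 ratio of SS to LS of -0.12 in pair 1 and 0.40 in pair 2, but 0.08 and 0.40 over the 200 with at least 10 counts in all, so the opposite sign rests on those of few reads. The value of 0.08 is the one that equal counts in both libraries of pair 1 give. A difference in scaling between the LS libraries is argued against, since known miRNAs had a median log2 of LS library 2 over library 1 of -0.00196 (bootstrap interval -0.04 to 0.01) while predicted ones had -0.49 (-0.07 over the 200). A candidate explanation is that the predicted miRNAs were chosen by their counts in LS library 1: 75.7% were lower in LS library 2 than in library 1 (exact interval 71.0% to 80.0%; 62.5% over the 200), against 52.4% lower in SS library 2 than in SS library 1. None had a count of 0 in LS library 1, against 55 in LS library 2. No biological explanation was tested, since both pairs compare the same lines.

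With the authors' library totals most known miRNAs were higher in SS. Whether a smaller share of other small RNAs in the SS totals contributed stays open. By the median log2 ratio to LS library 2, predicted miRNAs stood at 0.396 in SS library 2 (bootstrap interval 0.18 to 0.49), where known ones stood at 0.40. In SS library 1 predicted miRNAs stood at 0.16 (0.16 to 0.22), the value that equal counts in both libraries give, where known ones stood at 0.39. Over the 200 predicted miRNAs with at least 10 counts in all, the medians were 0.396 in SS library 2 and 0.328 in SS library 1. Most of the gap in SS library 1 thus lay in those of few reads. The value of 0.396, identical in both selections, is also a step that small whole counts give. Its closeness to 0.40 therefore carries little weight. A general rise of miRNAs in the short-silique line would give the same values, and it stays open and untested.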
